A study of Mus musculus with 4 samples.

How the data were processed

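Whole kidney RNA of 4 mouse samples was hybridized to single-colour Affymetrix whole-genome arrays, per the labels: 1 TgFVB and 1 FVB array at 6 weeks and 1 of each at 8 weeks. FVB is an inbred mouse strain. TgFVB is not defined in the labels; from knowledge of the study it is an FVB line that carries an HIV-1 transgene and develops kidney disease. The labels give neither the sex of the animals nor how many kidneys or animals stand behind an array. The p-values therefore measure the spread between these arrays, which may be technical.

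The main table holds deposited intensity values on a linear scale, 1 per probe set, for 45101 probe sets of which 64 are controls. The mean signal trimmed by 2% at each end was 250 on each of the 4 arrays, so the deposited table had been scaled per array; neither the labels nor the headers state the algorithm. Per the submitters' processing notes, RMA was used for the TgFVB array at 6 weeks and GCRMA for the other arrays, with no version, and the linear values of the main table do not have the form of either. The second table holds deposited log2 values for 15768 gene rows and 64 control rows, with a floor at 2.32 (a signal of 5). Its rows carry Ensembl identifiers that no supplied reference pairs with a name, so it gave counts of rows and no named gene. The design had foreseen log2 RMA values as the main table; the intensity table was used because it held more probe sets, as the design prescribed, and its values were put on the log2 scale first.

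Probe sets were named from the array's annotation, and 34945 were listed with 1 gene. Another 932 with several genes and 9160 with no gene were left out of the named results. Symbols were looked up by gene identifier in the RefSeq annotation of GRCm38.p6, which changed 0 symbols and held no entry for 204 of the probe sets. The probe set with the highest mean stood for a gene, which gave 18193 genes. The 30% with the lowest mean log2 signal were left out (a geometric mean signal of 33.0 or below), leaving 12735 genes tested.

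Genotype and age were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. This fit leaves 1 residual degree of freedom, which holds both array noise and any change of the genotype difference with age. eBayes therefore draws nearly all of its spread from a prior estimated across genes, with 15.1 prior degrees of freedom. On simulated data with 200 of 12735 genes changed and that same prior, the genotype fit recovered 8.60% of the genes changed 2-fold, 80.5% of those changed 4-fold and 99.5% of those changed 8-fold. In those 20 simulations 14.0% of the calls were false, above the nominal 5%. With no gene changed, a mean of 2.05 and at most 9 genes were called, and the estimated prior ran from 9.70 degrees of freedom upwards without bound. The simulated genes were independent, with the same spread on all 4 arrays and no effect of age. In the real data the standard deviation of the genotype difference across genes was 0.447 at 6 weeks and 0.845 at 8 weeks. The simulations therefore do not give the share of false calls among the genes called in the real data. The precision of every value is limited by the number of arrays.

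Before the data were examined, 29 gene lists for kidney segments, injury, immune and other cell types, sex and stress were fixed. Of these, 27 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. At each age a list's median difference was placed among 10000 random lists matched on mean expression in 20 bins. Genes at least 2-fold different in the same direction at both ages were counted without a test, and the change of the genotype difference from 6 to 8 weeks is given as values.

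Genes were named by a rule fixed at the same time: Lcn2, the product of which is NGAL; up to 12 genes in each direction of the genotype fit with the same sign at both ages, with places left filled by genes that did not pass; 5 in each direction for age; 5 in each direction for the change with age; and up to 4 members of a list. Members are named for the lists called by genotype and for the podocyte and neutrophil lists. The lists themselves were fixed beforehand, but the limit to these lists for naming members was set after the values were seen. The clock genes and the first group of glucocorticoid-responsive genes were also chosen after the values were seen. The 4 genes past the threshold beyond the first 12 are named as well. The 4 X-linked genes that escape inactivation were chosen after the data were seen but before their own values were.

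The alternatives were a fit without the second factor, an intensity trend in the prior, no filter and a 50% filter, the mean of a gene's probe sets, every probe set on its own, no probe sets of the less specific kinds, quantile normalization, centring on the median, the second table, other fold thresholds, other list tests and leaving out each array. Raising signals under 32 to 32 was added after the data were seen.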

Results

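Expression was measured in whole kidneys of TgFVB and FVB mice at 6 and 8 weeks, with 1 array per genotype and age, so 4 arrays in all. The median signal lay between 51.8 and 64.2 intensity units on the 4 arrays. Across the 12735 genes tested, the rank correlation between the TgFVB and FVB arrays was 0.980 at 6 weeks and 0.913 at 8 weeks. The TgFVB array at 8 weeks stood apart from the other 3, with rank correlations of 0.913 to 0.919. For Pcx and Actb the ratio of 3' to 5' control signal, which RNA integrity affects, differed between the genotypes in opposite directions at the 2 ages. For Pcx it was 5.77 in TgFVB and 9.27 in FVB at 6 weeks, and 10.9 and 5.05 at 8 weeks. For Actb it was 2.93 and 4.59, and 4.31 and 2.58. The Gapdh ratio was higher in TgFVB at both ages, 0.852 against 0.844 and 0.928 against 0.781. Correlations across genes describe the arrays, since genes are not independent replicates. No 2 arrays shared both genotype and age.

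The first comparison asked which genes differ between TgFVB and FVB kidneys; the series names NGAL, the product of Lcn2, among those most highly raised. Lcn2, which encodes a secreted iron-carrier-binding protein of injured tubules and neutrophils, had the largest fitted difference of the genes tested, 6.36 on the log2 scale (SE 0.42, n = 2 arrays per genotype, limma adjusted p = 7.2e-07). It missed the threshold in 6 of the 12 settings chosen before the data were seen, among them no age term (adjusted p = 0.624), no filter and every probe set on its own (adjusted p = 0.204). Its signal was 582 in TgFVB against 9.45 in FVB at 6 weeks, and 2376 against 21.8 at 8 weeks. The FVB signals lie in the dim range, below the 33.0 of the filter, so the size depends on them; with signals under 32 raised to 32, a setting chosen after the data were seen, the difference was 5.20. Havcr1, the tubular injury marker KIM-1, rose by 3.18 (adjusted p = 0.00833) and Cd44, a hyaluronan receptor, by 3.02 (adjusted p = 0.00967). The fibrinogen gamma chain gene Fgg reached a signal of 10851 in the TgFVB kidney at 8 weeks against 535 in FVB, and its fitted difference was 3.07 (adjusted p = 0.0281).

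In all, 16 genes rose in TgFVB and 0 fell by limma at adjusted p under 0.05; at an unadjusted p under 0.05, 410 were higher and 259 lower. All 16 were higher in TgFVB at both ages. Beyond those above they were the transcription factor genes Fos (3.76) and Atf3 (2.33), the protease inhibitor genes Serpina3n (3.58) and Serpina10 (2.89), Ltbp2 (3.15), Ubd (3.08), H3f3b (2.88), the diamine oxidase gene Aoc1 (2.48), the complement factor I gene Cfi (2.45), the chemokine gene Cxcl17 (2.45), the metalloproteinase inhibitor gene Timp1 (2.42) and the adhesion molecule gene Vcam1 (2.36). Of the 16, 9 had an FVB signal below the 33.0 of the filter, so their sizes depend on dim signals; Ltbp2 read 9.15 units in FVB at 6 weeks and 15.6 at 8 weeks, and Cxcl17 8.11 and 40.2, and with signals under 32 raised to 32 their differences were 1.73 and 1.46. The number called was 0 with no filter, 79 higher and 23 lower with the lowest 50% left out, 0 when age was left out of the fit, 0 in the second deposited table, and between 0 and 53 higher when 1 array was left out. Without the TgFVB kidney at 8 weeks the difference was 0.96 for H3f3b, 1.59 for Fgg, 1.59 for Cfi, 1.97 for Ltbp2, 2.03 for Ubd and 2.04 for Serpina3n; it was 2.44 for Fos without the FVB kidney at 8 weeks and 1.29 for Cxcl17 without that at 6 weeks. Fits without 1 array, here and below, have no second factor, so age is unbalanced between the genotypes. Between arrays of the same age, H3f3b differed by 1.59 at 6 weeks and Cxcl17 by 2.17 at 8 weeks.

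**Figure D1:**
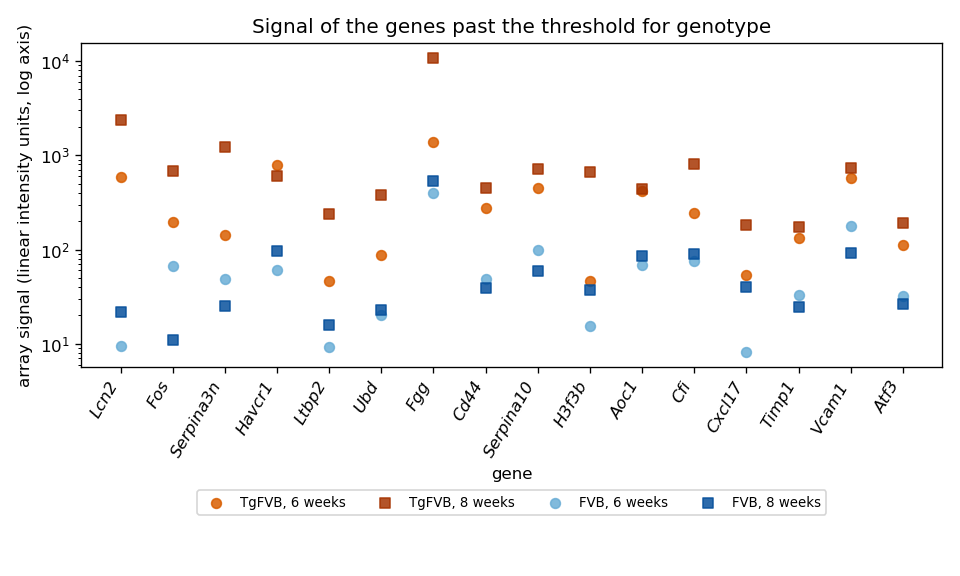
Signal of the 16 genes past the threshold for genotype on each of the 4 arrays (intensity units, log axis; 1 point per array, no error bars). Both TgFVB points lie above both FVB points for each of the 16 genes, with Lcn2 at 582 and 2376 against 9.45 and 21.8.

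No gene passed in the lower direction, and the genes that fill those places are given as values only. The nuclear receptor gene Nr0b2 was -1.60 at 6 weeks and -1.59 at 8 weeks, H2bc18 was -1.43 and -1.46, and Ces2e was -1.15 and -1.98. The muscle-type glycogen phosphorylase gene Pygm was -1.02 and -3.13, and Perm1 -1.01 and -2.57. Nrip3, Marchf9, Apbb1ip, Veph1, Itih2, Ipcef1 and Zfat had fitted differences between -1.56 and -1.07. Adjusted p ranged from 0.230 for Pygm to 0.718 for Itih2.

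Counted by fold without a test, 74 genes were at least 2-fold higher and 13 at least 2-fold lower in TgFVB at both ages. Independent ages would give 29.9 and 26.4 when counted within 10 bins of mean expression. Another 81 genes were at least 2-fold lower at 6 weeks and at least 2-fold higher at 8 weeks, against 58.3 for independent ages, and 12 were higher and then lower, against 15.8. At 6 weeks 179 genes were at least 2-fold higher and 300 lower, against 1281 and 1080 at 8 weeks. The correlation of the differences at the 2 ages across genes was -0.02. The second deposited table gave 42 higher and 10 lower, and no filter gave 421 and 252.

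Of 27 gene lists, 9 were called higher and 3 lower in TgFVB by camera at the preset correlation. The macrophage list had a median of 1.54 (0.53 at 6 weeks and 2.62 at 8 weeks; 0.71 to 2.34 when 1 array was left out), with 14 of 16 members higher at both ages, and the immediate early list one of 1.41 (0.73 and 2.20; 0.81 to 2.04). None of the macrophage members passed over all genes tested and 13 were higher adjusted over the list alone; the complement gene C1qc was 1.29 at 6 weeks and 3.49 at 8 weeks, and the lysozyme genes Lyz2 and Lyz1 were 1.13 and 3.48, and 0.73 and 3.81. Camera gave an adjusted p of 2.9e-23 for the list, and adjusted p = 0.693 with an estimated correlation. That same adjusted p of 0.693 with an estimated correlation holds for each of the 12 lists called, so none of the calls passed that test. It holds for the podocyte list too, which was not called. With 1 residual degree of freedom the test has little power, so it cannot decide whether the calls hold. Fry, on the same 1 residual degree of freedom, gave 0 lists with p under 0.05. The calls therefore rest on the preset correlation alone.

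In the tubular injury and repair list 5 of 25 members rose over all genes tested and 14 adjusted over the list alone, where 1 fell (camera adjusted p = 2.4e-22). Its median was 0.38 at 6 weeks and 1.70 at 8 weeks. In the immediate early list, genes that cells switch on within minutes of a stimulus, 1 of 13 members rose over all genes and 9 adjusted over the list alone (adjusted p = 5.4e-21); Egr1 was 0.82 at 6 weeks and 3.97 at 8 weeks, Klf6 0.67 and 3.21, and Zfp36 0.74 and 2.85. In the extracellular matrix and fibroblast list 1 of 32 members rose over all genes and 8 adjusted over the list alone (adjusted p = 1.7e-20), and 25 were higher at both ages; Col1a1 was 1.42 at 6 weeks and 3.03 at 8 weeks, Lox 0.06 and 3.51, and Fn1 0.93 and 2.34. In the complement and acute phase list 2 of 15 members rose over all genes and 8 adjusted over the list alone (adjusted p = 3.3e-13); Fgb was 1.31 at 6 weeks and 3.84 at 8 weeks, and Fga 0.78 and 3.26. In the chemokine, cytokine and NF-kB target list 1 of 18 members rose over all genes and 3 adjusted over the list alone (adjusted p = 1.4e-09); Icam1 was 1.36 at 6 weeks and 2.20 at 8 weeks, and Cxcl10 1.59 and 1.36.

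The cell cycle list had medians of 0.52 at 6 weeks and 0.37 at 8 weeks, with 0 of 29 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 2.4e-06). Kif2c was 0.41 at 6 weeks and 2.35 at 8 weeks, Rrm2 0.52 and 1.87, Birc5 1.29 and 0.95, and Foxm1 0.24 and -2.67. The B cell and plasma cell list, with Jchain at -0.07 and 2.29 and Blnk at 0.22 and 1.49 at the 2 ages, was called higher at adjusted p = 0.0495; its median was -0.24 at 6 weeks and 1.40 at 8 weeks, and without the TgFVB kidney at 8 weeks its fitted median was -0.14.

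The proximal tubule list was called lower (camera adjusted p = 0.00361), with 0 of 36 members past the threshold over all genes or adjusted over the list alone. Its median was 0.09 at 6 weeks, with 22 members higher, and -0.65 at 8 weeks, with 27 lower. Among matched random lists these medians lay at percentiles 99.97 and 0, so the direction of the list reversed between the ages. The fitted median was 0.04 when the TgFVB kidney at 8 weeks was left out, so the call rests on that kidney. The megalin gene Lrp2 was -0.04 at 6 weeks and -2.40 at 8 weeks, Gatm 0.49 and -2.50, the organic anion transporter gene Slc22a6 0.48 and -2.35, and the urate transporter gene Slc22a12 -0.77 and -1.39. For Lrp2, 3 probe sets lay above the filter, with fitted differences from -1.33 to -0.33. The 3' to 5' ratio of Pcx was highest, 10.9, in the TgFVB kidney at 8 weeks, while that of Actb was highest, 4.59, in the FVB kidney at 6 weeks.

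The other 2 lists called lower and 1 called higher were the sex lists. The Y-linked and Xist list (adjusted p = 0.00361) had a median of -0.70, which rests on dim signals: at 6 weeks Eif2s3y read 1.21 units in TgFVB and 21.1 in FVB, and Kdm5d 6.48 and 14.0. Eif2s3y was -4.13 at 6 weeks and 0.52 at 8 weeks, and with signals under 32 raised to 32 the list had a median of -0.35. The male-biased kidney list (adjusted p = 0.0495) had medians of 0.0076 at 6 weeks and -0.30 at 8 weeks, with Slco1a1 at 0.52 and -2.79 and Slc7a13 at 1.06 and -3.22. The female-biased list (adjusted p = 0.00537) had medians of -0.38 and 2.41, with 0 and 3 of 3 members higher; Cyp4a14 was -0.70 and 3.52. None of their 4, 10 and 3 members passed over all genes or adjusted over the list alone.

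The podocyte list was not called (adjusted p = 0.267), with medians of 0.02 and -0.17; its members with the largest fitted differences were Rhpn1 (1.15 at 6 weeks and -3.08 at 8 weeks), Kirrel (0.25 and 1.59), Tcf21 (0.46 and -2.28) and Foxd1 (-0.17 and -1.50). Lists for thick ascending limb (adjusted p = 0.0994), distal convoluted and connecting tubule (0.283), collecting duct (0.210), endothelium (0.559), fatty acid oxidation (0.351), interferon response (0.267), hypoxia and glycolysis (0.201) and endoplasmic reticulum stress (0.128) were not called. Nor were those for iron handling (0.817), nephron development (0.817), T cells (0.648), neutrophils (0.110), adipose tissue (0.0659) and housekeeping genes (0.594). The erythrocyte and adrenal gland lists had 2 and 1 tested members and were not tested.

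**Figure D2:**
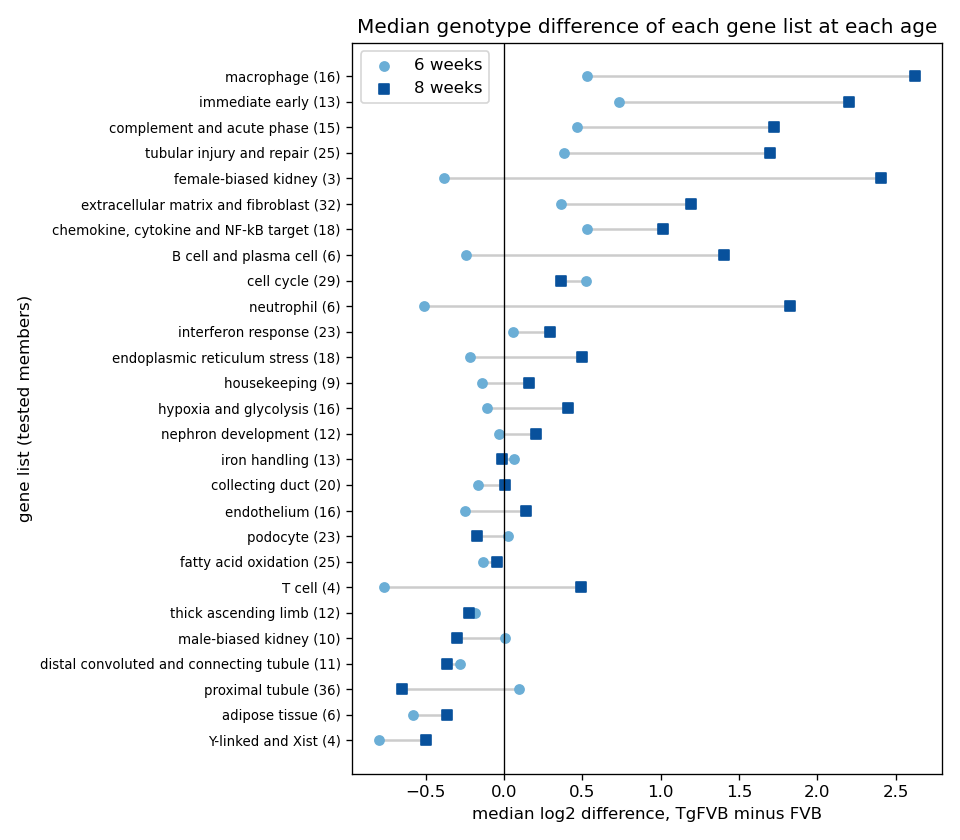
Median log2 difference between TgFVB and FVB for each of the 27 gene lists tested, at 6 weeks (circles) and 8 weeks (squares), from 1 array per genotype and age and so with no error bars. The macrophage list lies at 0.53 and 2.62, the proximal tubule list at 0.09 and -0.65.

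The second comparison, of 8 with 6 weeks, was led by sex-linked and sex-biased genes. Xist, the RNA of the inactive X chromosome, fell by 4.75 (adjusted p = 1.7e-05), while the Y-linked genes Eif2s3y (6.67), Kdm5d (4.29) and Uty (2.56) rose (adjusted p = 0.000103, 3.9e-05 and 0.00709). All 3 were under 32 units on both arrays at 6 weeks, so the sizes depend on dim signals; with signals under 32 raised to 32 they were 4.003, 2.54 and 2.39. In the male-biased kidney list 5 of 10 members rose, among them Slc7a13 (6.08), Cyp2j13 (5.30), Slco1a1 (5.09) and Acsm3 (4.61). Of the 3 tested members of the female-biased list Slc7a12 fell by 3.99 (adjusted p = 0.00109), and Cyp4a14 and Abcc3 were -1.23 and -1.73. Both arrays at 6 weeks thus had high Xist (1560.2 and 2182 units) and both arrays at 8 weeks low Xist (59.4 and 78.8 units).

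The same comparison gave 33 genes that rose and 16 that fell, all 49 in the same direction in both genotypes. Cyp7b1, also of the male-biased kidney list, rose by 5.75, Ugt2b37 by 5.70 and Apoh by 5.35. Atp13a4, Thrsp and Dagla fell by 3.79, 3.12 and 2.73. Without 1 array Atp13a4 ran from -5.34 to -2.24 and Dagla from -3.69 to -1.77. Atp13a4 read 26.5 and 3.09 units in TgFVB and FVB at 8 weeks, and Apoh 5.71 and 27.9 at 6 weeks; with signals under 32 raised to 32 Atp13a4 was -1.97 and Apoh 4.003. The hybridization controls, bacterial and phage transcripts added to each sample, differed between the ages by a median of -2.93 on the log2 scale, against -0.21 and 0.77 between the arrays of an age. Age, the sex markers and this difference coincide on the 4 arrays. The counts were 0 and 0 when genotype was left out of the fit, and ran from 2 to 249 and from 0 to 450 when 1 array was left out.

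**Figure D3:**
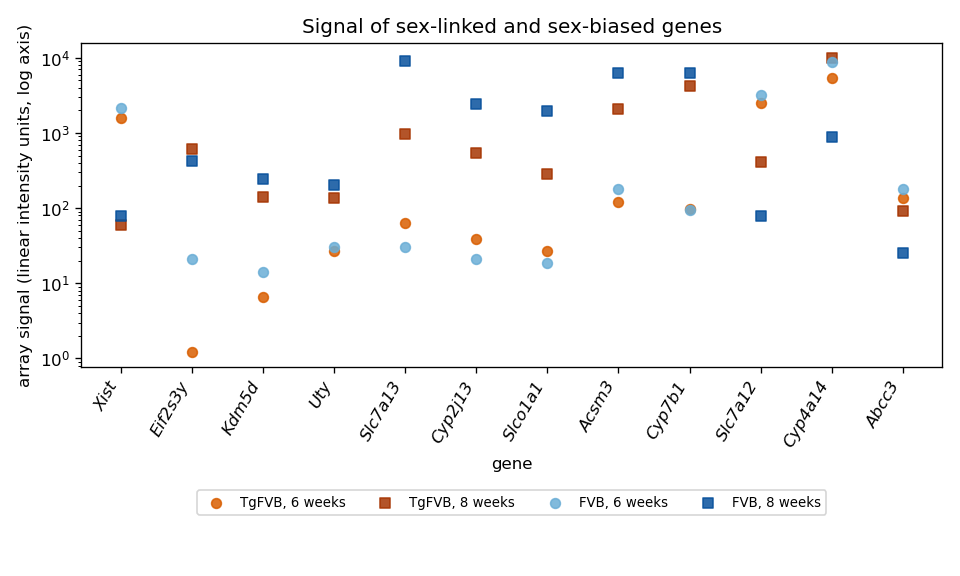
Signal of sex-linked and sex-biased genes on each of the 4 arrays (intensity units, log axis; 1 point per array, no error bars). Xist lies at 1560.2 and 2182 in the kidneys at 6 weeks and at 59.4 and 78.8 in those at 8 weeks.

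The change of the genotype difference from 6 to 8 weeks can be given as values only. The 2 ages also differ in the sex markers and the hybridization controls, so these values cannot be put down to age alone. The largest increases were in the chemokine gene Ccl8 (6.22), the neutrophil gene S100a9 (6.15), Rgs1 (5.64), Panx1 (5.34) and the urinary protein gene Mup10 (5.14). The largest decreases were in Zfp748 (-4.69), Crocc (-4.44), Atxn7l2 (-4.40), Tfec (-4.38) and Cyp4a12a (-4.36). Several of these start from dim signals; S100a9 read 6.04 units in TgFVB and 44.2 in FVB at 6 weeks. Of the neutrophil list, S100a8 was -0.10 at 6 weeks and 3.64 at 8 weeks, Ngp -0.80 and 2.07, and Mmp9 -0.22 and 0.70. The standard deviation of the genotype difference across genes was 0.447 at 6 weeks and 0.845 at 8 weeks.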

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

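The tests of a hybridization batch, Lcn2 and the sex-biased genes in TgFVB were chosen after the results they concern were seen; that of 4 X-linked genes was written down before their values were looked at. For the named genes, a difference of at least 2-fold between TgFVB and FVB that pointed one way at 6 weeks and the other way at 8 weeks was singled out, as was a list median of at least 0.3 on the log2 scale at each age with opposite signs. With 1 array per genotype and age, none of these differences between ages was tested. The ages also differ in the sex markers and the hybridization controls, so a change with age cannot be told apart from either.

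The change from 6 to 8 weeks was 6.22 for Ccl8, 6.15 for S100a9, 5.64 for Rgs1, 5.34 for Panx1, 5.14 for Mup10 and 5.13 for Apoh, all from lower to higher in TgFVB. It was -4.69 for Zfp748, -4.40 for Atxn7l2, -4.28 for Slc7a13 and -4.23 for Rhpn1, from higher to lower. Among the lists, the median moved by 2.78 for the female-biased kidney list (-0.38 to 2.41), by 2.33 for the neutrophil list (-0.51 to 1.82) and by 1.26 for the T cell list (-0.77 to 0.49).

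The arrays at 6 and 8 weeks differ in Xist, Y-linked and sex-biased genes. Signed by sex bias, with signals under 32 raised to 32, the 17 genes had a median difference of 2.54 towards the male pattern at 8 weeks. In 10000 random lists matched on mean expression it was at most 0.41. In FVB 17 of 17 went that way and in TgFVB 16 of 17. These genes define the pattern and the test was chosen after it was seen, so it is no separate evidence. The sex lists were, however, fixed before the data were examined. The values argue against a hybridization batch that moves genes without regard to their sex bias. That holds for the cause of this pattern only. Xist and the Y-linked genes had the female pattern on both arrays at 6 weeks and the male pattern on both at 8 weeks. The labels give no sex. Sex of the animals was tested further on Kdm6a, Kdm5c, Eif2s3x and Ddx3x, X-linked genes that escape inactivation and so run higher in females. From 6 to 8 weeks these differed by -0.38, -1.15, -0.54 and -0.07. Their median of -0.46 lay at percentile 3.13 of matched random lists, short of the 2.5 set in advance. That bound was reached by 6 of 24 lists not concerned with sex. The test of these 4 genes therefore cannot decide for or against sex. The signals of Xist and the Y-linked genes do bear on it. At 6 weeks Xist read 1560.2 and 2182 units in TgFVB and FVB, and Eif2s3y 1.21 and 21.1. At 8 weeks Xist read 59.4 and 78.8, and Eif2s3y 614 and 429. Kdm5d and Uty also rose in both genotypes. These values argue against animals of 1 sex on all 4 arrays. A difference in sex between the ages stays a candidate explanation that the labels do not settle. The effect of age itself stays untested, and whether a batch lies behind the difference of -2.93 in the hybridization controls, and moved other genes, cannot be told from labels that name none.

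Lcn2 is higher in TgFVB at both ages. Dim signal in FVB as the whole cause is argued against: with signals under 32 raised to 32, the smaller of the differences at the 2 ages was still 4.18. Neutrophils as its source at 6 weeks were tested on S100a8 and S100a9, abundant neutrophil transcripts, of which the higher difference was -0.10. S100a9 read only 6.04 units in TgFVB. All 6 tested members of the neutrophil list were lower at 6 weeks (median -0.51). Of the members left out by the filter, Camp (2.997), Elane (1.82) and Mmp8 (1.61) were higher, and Cxcr2 (-1.06) and Csf3r (-1.46) lower. With dim signals and 1 array per genotype, the test cannot decide for or against neutrophils at 6 weeks. At 8 weeks the higher of the S100a8 and S100a9 differences was 3.64, so a share from neutrophils could be present at that age. It cannot be told apart from tubular expression in whole kidney RNA.

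In the TgFVB kidney at 8 weeks some male-biased genes were lower than in FVB (Slc7a13 -3.22, Slco1a1 -2.79, Cyp2j13 -2.18, Acsm3 -1.59) and female-biased genes higher (Cyp4a14 3.52, Slc7a12 2.41), although the male-biased list as a whole had a median of only -0.30. Female RNA in that sample is argued against by Xist, whose 2 probe sets had a median difference of -1.28. Fewer proximal tubule transcripts would not by themselves raise the female-biased genes, of which the lowest difference was 1.87. That rise is part of the pattern and so no separate test. For the male-biased part, fewer proximal tubule transcripts may still hold, since the list's median lies 0.35 above that of the proximal tubule list and its members go both ways. A hormonal difference between the animals was not tested.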

How the results depend on the processing

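The direction of the Lcn2 difference was the same under every alternative that measured it, with a fitted difference of 5.20 to 7.37. Its adjusted p was not: it missed the threshold, with the difference at 6.36, when age was left out (0.624), with no filter and with every probe set on its own (0.204), and it passed in 6 of the 12 settings chosen before the data were seen, with a range from 3.5e-45 to close to 1. Its range without 1 array was 5.34 to 7.37, where only leaving out the TgFVB kidney at 6 weeks kept it past the threshold (0.0270). Its single probe set is of the less specific kinds, so leaving these out gave no value. The other 15 genes past the threshold kept their direction under each alternative but passed it in at most 4 of the 12 or 13 such settings, and Cxcl17 in 0. Of the 16, 8 moved by over 1.5 times without 1 array, among them Serpina3n (2.04 to 5.12), Fgg (1.59 to 4.55) and H3f3b, the lowest at 0.96; Lox, which did not pass, ran from 0.13 to 3.44.

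The prior's degrees of freedom ran from 0.676 in the second table to no bound with an intensity trend, but the counts did not simply follow it: at 5.44 there were 53 higher without the TgFVB kidney at 6 weeks and 0 without that at 8 weeks. For genotype, higher and lower were 0 and 0 with no age term, 88 and 22 with an intensity trend in the prior, 0 and 0 with no filter, 79 and 23 with the lowest 50% left out, 1 and 0 with the mean of a gene's probe sets or with quantile normalization, 0 and 0 with every probe set on its own, without the less specific probe sets or in the second table, and 10 and 0 with median centring. For age they were 0 and 0 with no genotype term, 83 and 101 with the trend, 0 and 0 with no filter, 68 and 91 with the 50% filter, 9 and 3 with the mean, 1 and 0 with every probe set, 13 and 3 without the less specific ones, 3 and 1 with quantile normalization, 0 and 0 in the second table, and 10 lower with median centring. With signals under 32 raised to 32, chosen after seeing the data, they were 70 and 12 for genotype, 75 and 77 for age; raising dim signals takes away their spread, so p-values of that setting are not relied on. Without 1 array the counts ran from 0 to 53 higher and 0 to 45 lower for genotype, and from 2 to 249 and 0 to 450 for age, where each array left out changed them; a lone array is then assumed to vary like the others.

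Genes at least 2-fold different at both ages numbered 421 higher and 252 lower with no filter, 28 and 1 with the 50% filter, 276 and 111 with every probe set, and 42 higher in the second table; lower were 31 with the mean, 21 without the less specific probe sets and 7 with signals raised to 32. At 1.5-fold they were 286 and 153, at 3-fold 17 and 1. Without 1 array this count cannot be made.

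The lists called were 0 and 0 with an estimated correlation, a test with little power at 1 residual degree of freedom. Those lower were 1 with no age term and with the mean of probe sets. Without 1 array, 7 to 8 were called higher and 2 to 4 lower. Fitted differences that reversed without 1 array ranged from -2.44 to 0.51 for Rhpn1, -2.20 to 0.38 for Tcf21, -2.46 to 0.020 for Lrp2, -2.50 to 0.49 for Gatm, -1.97 to 0.10 for Slc22a6, -0.49 to 1.17 for Mzb1, -0.61 to 1.88 for Ngp, -0.094 to 0.58 for Mmp9, -2.71 to 3.12 for S100a9, -0.17 to 4.05 for Ccl8, -2.43 to 0.010 for Foxm1, -6.30 to 2.69 for Eif2s3y, -3.18 to 1.27 for Kdm5d, -2.84 to 1.95 for Xist, -1.76 to 1.01 for Uty, -4.50 to 2.24 for Slco1a1, -5.19 to 3.03 for Slc7a13, -3.64 to 1.49 for Acsm3, -4.06 to 2.77 for Cyp2j13, -0.26 to 3.08 for Cyp4a14, -1.63 to 3.72 for Slc7a12 and -0.68 to 2.17 for Abcc3. With signals raised to 32 Eif2s3y was 0.26. List medians that reversed ranged from -0.66 to 0.040 for proximal tubule, -0.14 to 1.16 for B cells, -2.39 to 1.03 for Y-linked and Xist, -2.15 to 1.15 for male-biased and -0.68 to 3.08 for female-biased. These fits have no second factor, so leaving out an array unbalances age between the genotypes; other causes were not tested. Signals near the dim end limit all counts.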

Other observations

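The gene sets in this part were chosen after the data were seen; the test of 8 further genes was written down before their values were looked at. In the TgFVB kidney at 8 weeks, genes known to respond to glucocorticoids were higher than in FVB, several of them not at 6 weeks: Cebpd was 0.31 at 6 weeks and 4.29 at 8 weeks, Cdkn1a 0.0060 and 4.12, Igfbp1 -1.55 and 3.48, Tsc22d3 1.19 and 2.60, Zbtb16 1.80 and 2.50, and Klf9 -0.83 and 2.17. Fkbp5 was 0.92 at 6 weeks and 1.40 at 8 weeks, and Sgk1 0.81 and 1.53. None passed the genotype test (adjusted p 0.0624 for Zbtb16 and 0.377 for Cebpd).

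Of 12 clock genes none passed the genotype test, with the lowest adjusted p at 0.255 for Cry1, so the following are values only. Ciart was -0.09 at 6 weeks and 3.95 at 8 weeks, Per1 -0.10 and 3.02, Nr1d1 -1.01 and 1.67, Dbp -0.08 and 0.93, Clock -0.19 and -0.40, and Npas2 -1.09 and -0.09. Per2 was 1.68 at 6 weeks and 1.54 at 8 weeks, and Cry1 1.69 and 1.71. Of 12 clock genes 10 were higher in TgFVB at 8 weeks and 5 at 6 weeks. The labels give no hour of collection.

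A glucocorticoid response in the TgFVB kidney at 8 weeks is a candidate explanation for the first group. It was tested on 8 glucocorticoid-responsive genes not looked at before, among which Ddit4 was 4.05, Mt2 2.64, Mt1 2.50, Klf15 2.17, Arrdc2 1.96, Errfi1 0.99, Hif3a -0.43 and Bcl6 -0.87. Their median of 2.06 lay at percentile 100 of 10000 random lists matched on mean expression, and 6 of the 8 were higher. That outcome is not specific: 11 of the 27 lists fixed beforehand, macrophage, matrix and tubular injury lists among them, also reached the percentile set in advance as the bound at 8 weeks, as did the clock genes. The test therefore leaves a glucocorticoid response open, a reading adopted after its result was seen. At 6 weeks the 8 genes lay between -0.20 and 0.55 with a median of 0.07, at percentile 81.1. The test rests on 1 TgFVB array that differs widely from the others, and several of the 8 genes also respond to other stresses.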
